A study of Homo sapiens with 41 samples.

How the data were processed

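The series holds RNA sequencing of a human embryonic stem cell line, H1 with a MYH6-mCerulean3 reporter, differentiated towards cardiomyocytes by small molecules: 7 µM of the GSK3 inhibitor CHIR99021, then 5 µM of the Wnt secretion inhibitor IWP2 from day 3 to day 5, and insulin from day 7. NF2 was targeted with guides against exons 1 and 4. The labels give 4 lines, WT1, WT2, KO1 and KO2, at days 0, 1, 5 and 14. Each line has 2 or 3 libraries per day, in all 41, 19 of WT and 22 of KO. Which guide made which line, and whether libraries of a line were separate cultures, is not stated. P-values on sums per line measure spread between lines, others between libraries. Libraries were made with a stranded total RNA kit after ribosomal RNA depletion.

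Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned with STAR to hg38, counted with HTSeq and tested with edgeR, with no versions given. The deposited count files hold unnormalised counts per gene, whole numbers for 57521 genes followed by the 5 HTSeq counters. The deposited table of the whole series holds FPKM values for 29788 genes. Each FPKM column was checked against the counts. Over 4239 genes with at least 200 counts it equals the counts divided by 1 factor per library and 1 length per gene, with an SD of the log2 factor across genes of 3e-10. Of the gene ids, 56919 matched GENCODE release 29, which gave coordinates and biotypes, and 602 had no symbol. The strand setting of the counting is not given in the sources used here. Protein coding genes held 95.2% of the counts and antisense genes 0.37%. Values of overlapping, antisense and paralogous genes are therefore uncertain.

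Gene counts per library ran from 4.87 to 46.95 M (M, mega) with a median of 15.54 M. Alignments outside any gene made up 23.63 to 38.07% of unique alignments, and ambiguous ones 9.9 to 19.27%. A floor of 3 counts corresponds to 0.064 CPM (counts per M counts) in the deepest library and 0.616 CPM in the shallowest. Intervals and floors cover counting error only. Where a group had no count of a gene, the fold is a lower bound against 3 counts over the group, written as at least that many fold. Where it had 1 to 3 counts, the ratio is given with its exact counting interval.

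Lines, not libraries, were replicates. Counts were summed per line and day into 16 sums of 16 to 68.3 M, in 8 groups of 2 lines. Genes were filtered with filterByExpr, which left 28054, scaled with TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (8 residual and 5.01 prior degrees of freedom, biological coefficient of variation 0.204). The fit had no line term, so days of a line counted as independent and shared a dispersion. P-values were two-sided and adjusted by Benjamini-Hochberg per comparison (threshold 0.05). Comparisons were KO against WT at each day, each WT time step, and the difference of KO and WT steps (the interaction). Levels are CPM, as mean ± SD of the 2 line sums of a genotype (n = 2), folds come from the fitted model, and log2 changes carry their standard error. KO1 against KO2 and WT1 against WT2 were tested on the 41 libraries in 16 groups (24364 genes, coefficient of variation 0.291).

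A list of 27 gene groups was fixed before the data were examined: pluripotency, primitive streak and mesendoderm, cardiac mesoderm, cardiac progenitor transcription factors, sarcomere, cardiac calcium handling with ion channels and hormones, YAP and TEAD targets, Hippo pathway components, adherens junction, tight junction and apical polarity, mesenchymal genes of the epithelial to mesenchymal transition, canonical Wnt targets, definitive endoderm and liver, neuroectoderm and neural, endothelium and blood, smooth muscle, epicardium, fibroblast and extracellular matrix, trophectoderm with amnion and surface ectoderm, paraxial and presomitic mesoderm, S phase, G2 and M phase, p53 targets, glycolysis and hypoxia, cholesterol synthesis, replication-dependent histones, and mitochondrially encoded genes. Of their members 547 had an id and 2 (H3C2 and H3C3) did not. Lists were tested with camera of limma 3.58.1 at the preset correlation between genes, which asks whether members rank higher or lower than other genes, and adjusted over the 27 lists and 4 days. The same test with an estimated correlation, and fry, were run beside it. The main p of fry asks whether members move one way on balance and its mixed p whether they change in either direction, and neither compares a list with other genes.

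Named genes were chosen by a rule fixed at the same time: NF2, the 8 largest rises and falls among passing genes with a symbol, at least 100 counts per line sum in the higher genotype and the same direction in all 4 pairings of a KO with a WT line, and up to 4 members with the smallest p in each list. Pseudogenes, small RNAs, mitochondrial genes and clone-based names were skipped in the first part. Any member of a list could be named as an example.

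The test was checked on simulated counts with known changes, drawn independently per gene and line sum from the mean of each day and the fitted dispersion. At day 5 it recovered 4.3, 34.5 and 89.3% of genes changed 1.5, 2 and 4-fold, with 6 false calls. Lasting differences between lines, single libraries that stand apart and correlation between genes are absent there. The check, also for lists, thus describes an idealised setting. A simulated list passed camera with no other of the 20 lists passing. Whether equal replicate numbers pair libraries was checked by correlating, across genes, residuals of libraries with the same number in different lines. At day 0 the 12 such pairs had r from 0.576 to 0.698, and 8 of 8 libraries were closest to one of their own number, so a fit with the replicate number as a block is given beside the day 0 result. At days 1, 5 and 14, 8, 8 and 4 of 15 pairs had r over 0.1. At day 1 none of the 6 pairs with WT1 did and 8 of the 9 among WT2, KO1 and KO2 (r up to 0.387), and at day 5 6 of the 7 pairs without KO2 did (up to 0.325). A partial pairing at these days is thus open. The fits on libraries do not model it, and the block is given beside the results of days 1 and 5 too. Genes are not independent replicates in these correlations.

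Alternatives were size factors of the RLE method, no filter on low counts, DESeq2 1.42.0, libraries as replicates with and without a replicate block, limma-voom with line as a random effect, limma on log2 FPKM with pseudocounts of 1 and 0.1 and without a filter, an estimated correlation for lists, each day alone, a fold threshold of 2, and leaving out each line and each library. Added after seeing the data were the third KO2 libraries of days 5 and 14 left out, line sums thinned to 16 M counts, and splits of the libraries by AFP level (5 CPM) and by multimapping (1.05 non-unique alignments per unique one). Those splits are groups of samples defined from the data, not groups of the study. Other splits of the same samples were tested in the same way as the real one. No library was left out of the comparisons.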

Results

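The series title names a screen that linked NF2 and adherens junctions to the cardiac lineage. The libraries analysed here follow lines labelled WT or KO for NF2 through a cardiac differentiation, and show which genes the lines labelled KO expressed differently at each stage. NF2 encodes merlin, a membrane and cytoskeleton adaptor upstream of the Hippo kinases. RNA was measured in 41 libraries of 4 lines derived from H1 embryonic stem cells, WT1 and WT2 (19 libraries) and KO1 and KO2 (22 libraries). They were sampled at day 0 (undifferentiated), day 1 (mesendoderm), day 5 (progenitors) and day 14, when WT cells expressed cardiomyocyte genes. Gene counts per library ran from 4.87 M (M, mega) in WT2 library 1 of day 14 to 46.95 M in WT2 library 2 of day 5. At day 14 they averaged 7.84 ± 2.07 M in WT (SD, n = 5 libraries) and 16.55 ± 5.59 M in KO (n = 6). Levels are counts per M counts (CPM) as mean ± SD of the 2 lines of a genotype (n = 2), and pairs of levels run from WT to KO. Positions are those of hg38 and GENCODE 29. List members are counted as adjusted over all genes, then as adjusted over the list alone.

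NF2 itself was examined first, as a check of the labels. NF2 (ENSG00000186575.17, chromosome 22, 29603556 to 29698598, plus strand, protein coding) was lower in KO2 than in WT at all 4 days. The difference was 10.09-fold at day 0, 4.97-fold at day 1, 4.5-fold at day 5 and 6.88-fold at day 14 (adjusted p = 6.06e-11, 5.14e-10, 5.07e-10 and 1.46e-12). The tests of a single KO line used libraries as replicates, so their p-values measure only the spread between libraries of a line. At day 5 KO2 held 14.8 ± 2.3 CPM of NF2 (SD, n = 3 libraries), against 66.5 ± 0.8 CPM in WT1 (n = 2) and 59.5 ± 10.3 CPM in WT2 (n = 3). KO1 held 74.6 ± 1.5 CPM (n = 3), and its difference from WT did not pass at any day. Its log2 values were -0.75, -0.13, 0.17 and -0.30 at days 0, 1, 5 and 14 (adjusted p = 0.39, 0.763, 0.463 and 0.148). With both KO lines together NF2 did not pass either (log2 -1.51 ± 0.92 at day 0 and -1.07 ± 0.92 at day 14). Gene-level counts do not read an edit, so they do not check the label of KO1.

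**Figure D1:**
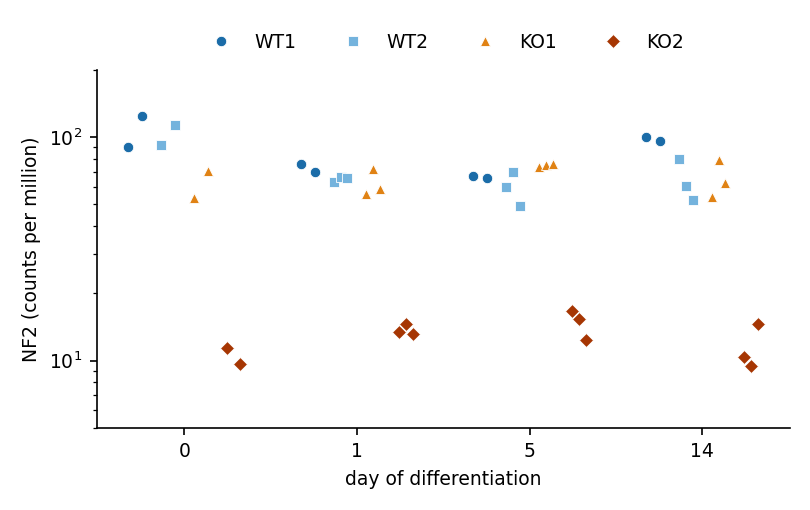
NF2 level in CPM (log axis) in each of the 41 libraries, by day, with 1 colour per line and 1 point per library. KO2 lies apart at each day, at 16.7 CPM or lower, and the libraries of the other 3 lines lie at 49.3 CPM or higher.

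The WT time course gives the reference against which KO is read. From day 0 to day 1 the WT lines turned on primitive streak genes, of which 20 of 22 rose (20 over the list alone). TBXT, the brachyury factor of early mesoderm, went from 0.303 ± 0.0407 to 325 ± 76.1 CPM, EOMES from 0.67 ± 0.271 to 565 ± 21.6 CPM and MIXL1 from 1.24 ± 0.484 to 1050 ± 41.3 CPM. Of the pluripotency genes 14 of 20 fell (14 over the list alone), such as FOXD3 (log2 -3.85 ± 0.40). Canonical Wnt targets (12 of 18 rose and 2 fell, 12 and 2 over the list alone) included DKK1 (log2 11.10 ± 0.53), and mesenchymal genes (10 of 20 rose and 1 fell, 11 and 1 over the list alone) included CDH2 (log2 3.44 ± 0.21). Replication-dependent histones were higher too (15 of 16 rose, 16 over the list alone).

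From day 1 to day 5 cardiac progenitor transcription factors came on in WT (16 of 20 rose and 1 fell, 16 and 2 over the list alone). NKX2-5, a homeobox factor of the early heart, went from 0.0501 ± 0.00245 to 72.7 ± 10.7 CPM. Sarcomere genes (20 of 25 rose and 1 fell, 20 and 2 over the list alone) and endothelium and blood genes (18 of 19 rose, 18 over the list alone) followed. WT2 libraries 1 and 3 of day 5 stood apart in sarcomere genes, with TNNT2 at 526 and 367 CPM and MYH6 at 280 and 316 CPM, against 9.51 to 13.1 CPM and 2 to 4.19 CPM in the other 3 WT libraries. Primitive streak (1 of 22 rose and 19 fell, 1 and 19 over the list alone) and pluripotency genes went down (16 of 20 fell, 17 over the list alone), with POU5F1 at log2 -5.46 ± 0.24. From day 5 to day 14 sarcomere genes increased further (24 of 25 rose, 24 over the list alone), with MYBPC3, a thick filament protein, going from 0.666 ± 0.318 to 555 ± 69.6 CPM. Calcium handling genes showed the same direction (20 of 24 rose and 1 fell, 20 and 1 over the list alone). G2 and M phase genes went down (20 of 20 fell, 20 over the list alone, MKI67 log2 -1.64 ± 0.15), as did S phase (18 of 20 fell, 18 over the list alone) and endothelium and blood genes (12 of 19 fell, 14 over the list alone). The tests passed 6710 genes (3118 higher, 3592 lower) for the first step, 11498 (5661 and 5837) for the second and 10674 (5122 and 5552) for the last. Without WT1 they passed 2946, 7062 and 6523 genes and without WT2 2631, 6973 and 6849. Here the lone WT line is assumed to vary like the other groups.

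**Figure D2:**
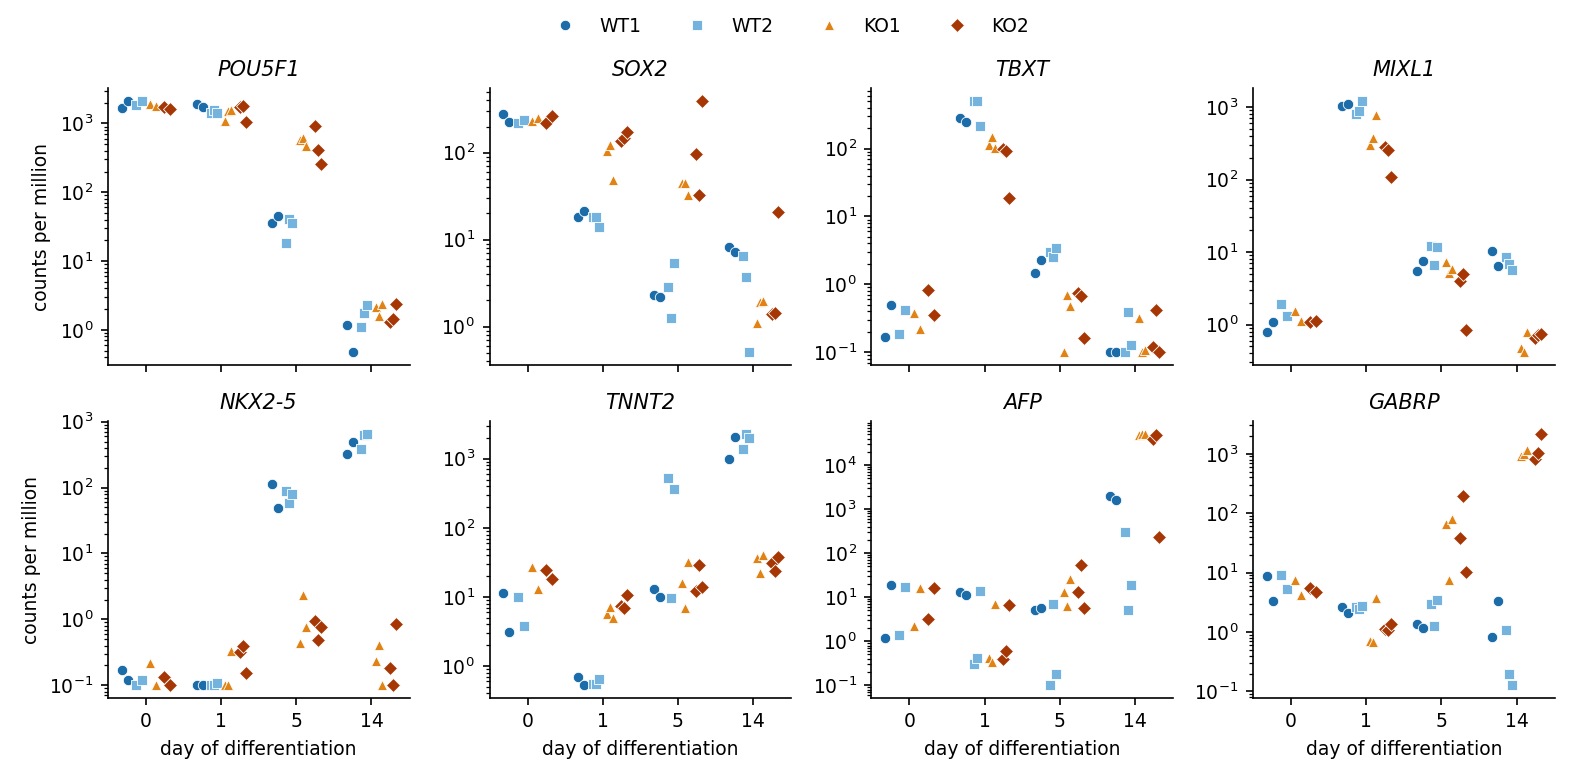
Levels in CPM (log axis, values under 0.1 drawn at 0.1) of 8 marker genes in each library, by day, with 1 colour per line and 1 point per library. At day 14 NKX2-5 lies at 328 to 653 CPM in WT and at or under 0.843 CPM in KO, and GABRP at 0.127 to 3.31 CPM in WT and 805 CPM or more in KO.

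Day 0 asks whether the undifferentiated lines labelled KO already differed from WT. On line sums 17 of 28054 genes passed, 16 of them higher in KO, and no gene of the pluripotency list was among them. POU5F1, the core pluripotency factor, lay at 1967 ± 145 CPM in WT and 1779 ± 122 CPM in KO (adjusted p = 0.973). CCDC125 (ENSG00000183323.12, chromosome 5, 69280175 to 69332809) rose 20.5-fold from 0.246 ± 0.0163 to 5.13 ± 0.622 CPM (adjusted p = 0.000945). Next came the galanin receptor GALR1 (10.1-fold, 0.582 ± 0.324 to 5.92 ± 1.03 CPM), the proteoglycan SPOCK3 (9.12-fold, 0.663 ± 0.052 to 6.07 ± 1.7 CPM), HHLA1 (6.93-fold, 1.95 ± 0.729 to 13.5 ± 1.32 CPM) and the SOX factor SOX15 (4.08-fold, 7.18 ± 0.927 to 29.3 ± 3.02 CPM). Smaller rises were those of the G protein regulator RGS5 (3.75-fold, 40.5 ± 1.9 to 152 ± 34.2 CPM), RIPOR2 (3.7-fold, 17.2 ± 1.76 to 63.8 ± 11.6 CPM) and the polarity protein PARD3B (2.49-fold, 8.81 ± 0.621 to 21.9 ± 1.4 CPM). GPCPD1, a phosphodiesterase of choline metabolism, fell 2.14-fold from 26.7 ± 6.31 to 12.5 ± 0.283 CPM. PKP2, MYF5, SOCS3 and PPME1 also passed and were named after their values were seen, and the other 4 had no symbol.

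CCDC125 and RGS5 passed at day 0 without any 1 library. The other named genes lost their call without some, most of them at a log2 near that with all libraries. GPCPD1 (log2 -1.10 with all libraries) did not pass without WT1 library 1 (log2 -0.51), WT2 library 1 (-0.90) or KO1 library 3 (-0.97). GALR1 and SPOCK3 did not pass without library 1 of WT1 (3.42 and 3.33), WT2 (3.29 and 3.23) or KO2 (3.08 and 3.15). HHLA1 and RIPOR2 did not pass without library 1 of WT2 (2.73 and 2.00) or KO2 (2.49 and 1.87), nor SOX15 without library 1 of WT1 or WT2 (2.00 and 2.06). PARD3B lost its call without library 1 of any line or KO2 library 3 (1.24 to 1.36). RGS5 (log2 1.91) and GPCPD1 (-0.91) did not pass in limma-voom, and PARD3B and SOX15 not on the log2(FPKM + 1) scale (0.77 and 1.89). With the replicate number as a block, which pairs libraries at day 0, 50 genes passed, and 170 in DESeq2 and 43 in limma-voom. Without the low-count filter 412 passed, and with day 0 fitted alone 536, of which 360 were higher and 176 lower, so the count and the excess of higher genes depend on the fit. In edgeR no gene passed without WT1, WT2 or KO2 (1514, 1951 and 981 at an unadjusted p under 0.05), and 4 without KO1. Leaving out 1 library gave 10 genes without WT1 library 1, 4 without WT2 library 1, 37 without WT2 library 3 and 7 without KO2 library 1.

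Among the lists at day 0 RGS5 was the 1 member called, in smooth muscle. Camera ranked 8 lists higher in KO at the preset correlation, and none of the 8 passed with an estimated one. They were p53 targets (no member of 20 passed, 3 rose over the list alone, adjusted p = 2.69e-07, adjusted p = 0.569 with an estimated correlation) and YAP and TEAD targets (no member of 22 passed, 3 rose over the list alone, adjusted p = 1.04e-06, adjusted p = 0.411 with an estimated correlation). Cholesterol synthesis was another (no member of 20 passed, nor over the list alone, adjusted p = 2.02e-05, adjusted p = 0.59 with an estimated correlation). Adherens junction (no member of 23 passed, 1 rose over the list alone, adjusted p = 0.00374, adjusted p = 0.59 with an estimated correlation), Hippo pathway components (no member of 26 passed, nor over the list alone, adjusted p = 0.00665, adjusted p = 0.603 with an estimated correlation) and smooth muscle (1 of 16 rose, 1 over the list alone, adjusted p = 0.0137, adjusted p = 0.59 with an estimated correlation) followed. The last were sarcomere (no member of 25 passed, 2 rose and 1 fell over the list alone, adjusted p = 0.0336, adjusted p = 0.725 with an estimated correlation) and mesenchymal genes (no member of 20 passed, 3 rose and 1 fell over the list alone, adjusted p = 0.0336, adjusted p = 0.59 with an estimated correlation). Members did not pass singly, as in AMOTL2 (86.3 ± 1.87 CPM in WT and 177 ± 14.3 CPM in KO, adjusted p = 0.475), CDKN1A (19.4 ± 0.407 CPM in WT and 40.7 ± 7.25 CPM in KO, adjusted p = 0.392) and CDH2 (59.2 ± 0.423 CPM in WT and 101 ± 6.53 CPM in KO, adjusted p = 0.301). Definitive endoderm did not pass (adjusted p = 0.945), and its fetal liver gene AFP stood at 15.9 to 19.1 CPM in library 3 and 1.18 to 3.25 CPM in library 1 of each line.

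Day 1 asks whether KO cells enter mesendoderm as WT cells do. Primitive streak genes were lower in the lines labelled KO, where 12 of 22 fell (1 rose and 16 fell over the list alone, adjusted p = 2.28e-19, adjusted p = 0.0175 with an estimated correlation). The brachyury gene TBXT (3.46-fold, 325 ± 76.1 to 93.9 ± 41 CPM), MIXL1 (2.89-fold, 1050 ± 41.3 to 364 ± 221 CPM) and EOMES (2.16-fold, 565 ± 21.6 to 262 ± 75.8 CPM) fell. MSGN1 (ENSG00000151379.3, chromosome 2, 17816496 to 17817101), a presomitic mesoderm factor, fell 135-fold from 46.2 ± 24.6 to 0.341 ± 0.145 CPM (adjusted p = 0.000141). Large falls were also in LHX1 (75-fold, 34.8 ± 4.88 to 0.462 ± 0.317 CPM), TBX6 (17.3-fold, 33.5 ± 11.1 to 1.94 ± 0.107 CPM) and the Wnt ligand WNT3A (13.8-fold, 35 ± 4.05 to 2.54 ± 1.45 CPM). In paraxial and presomitic mesoderm 8 of 20 fell (9 over the list alone, adjusted p = 1.85e-12, adjusted p = 0.0403 with an estimated correlation), with the Notch pathway genes DLL3 (8.73-fold, 87.5 ± 26.5 to 10 ± 1.47 CPM) and LFNG (7.67-fold, 51 ± 12.9 to 6.65 ± 0.101 CPM). Other lists hold 6 members of the primitive streak list and 5 of the paraxial list. Of cardiac mesoderm genes 8 of 20 fell (1 rose and 13 fell over the list alone, adjusted p = 3.3e-10, adjusted p = 0.125 with an estimated correlation). They included the apelin receptor APLNR (43.2-fold, 306 ± 158 to 7.09 ± 6.13 CPM), the Wnt agonist RSPO3 (43-fold, 25 ± 16.3 to 0.582 ± 0.272 CPM) and PDGFRA (28.1-fold, 60.7 ± 39.9 to 2.17 ± 1.01 CPM). MESP1 lay at 6.25 ± 6.79 CPM in WT and 1.01 ± 0.0772 CPM in KO (adjusted p = 0.0839). APELA, which encodes a ligand of the apelin receptor, rose 22.4-fold from 1.81 ± 0.525 to 39.8 ± 18.3 CPM.

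Pluripotency genes were higher in KO at day 1, as 4 of 20 rose (4 over the list alone, adjusted p = 0.00129, adjusted p = 0.376 with an estimated correlation). NANOG (3.44-fold, 56.8 ± 26.1 to 195 ± 25.4 CPM) and SOX2 (6.85-fold, 18.1 ± 2.28 to 124 ± 48.1 CPM) rose, and POU5F1 lay at 1670 ± 261 CPM in WT and 1473 ± 31.1 CPM in KO (adjusted p = 0.701). YAP and TEAD targets, read-outs of Hippo signalling, were higher, as 8 of 22 rose (9 over the list alone, adjusted p = 5.4e-11, adjusted p = 0.247 with an estimated correlation). The matricellular genes CCN2 (6.99-fold, 7.11 ± 0.247 to 49.7 ± 4.96 CPM) and CCN1 (4.68-fold, 5.13 ± 1.6 to 24.2 ± 2.25 CPM) rose, with the receptor kinase AXL (3.28-fold, 19.5 ± 2.91 to 63.8 ± 2.35 CPM). Hippo pathway components (6 of 26 rose, 7 rose and 1 fell over the list alone, adjusted p = 0.00231, adjusted p = 0.59 with an estimated correlation) included TEAD1 (1.97-fold, 128 ± 8.04 to 253 ± 6.93 CPM) and AJUBA (3.77-fold, 30.1 ± 0.643 to 114 ± 2.41 CPM). Of adherens junction genes 3 of 23 rose and 2 fell (5 and 2 over the list alone, adjusted p = 0.101). There NECTIN1 (1.98-fold, 25.4 ± 2.33 to 50.3 ± 1.21 CPM) rose, and the beta-catenin gene CTNNB1 (1.77-fold, 1173 ± 97.5 to 662 ± 7.36 CPM) and the N-cadherin gene CDH2 (1.92-fold, 641 ± 41 to 333 ± 70.2 CPM) fell. Tight junction genes (3 of 24 rose, 6 over the list alone, adjusted p = 0.00305, adjusted p = 0.681 with an estimated correlation) included CLDN3 (3.56-fold, 3.32 ± 0.15 to 11.8 ± 2.66 CPM). Canonical Wnt targets split, as 4 of 18 rose and 3 fell (7 and 3 over the list alone, adjusted p = 0.476). The secreted Wnt inhibitor DKK1 (14.1-fold, 1257 ± 579 to 89.2 ± 42.2 CPM) fell, and RNF43 (6.16-fold, 5.8 ± 0.336 to 35.8 ± 6.35 CPM), which removes Wnt receptors, rose. The median and mean of that list and of epicardium lay below 0 while the test pointed up.

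Some genes of later cell types were also higher in KO at day 1. Of sarcomere genes 6 of 25 rose (6 over the list alone, adjusted p = 8.85e-06, adjusted p = 0.411 with an estimated correlation), with TPM1 (4.06-fold, 105 ± 2.45 to 428 ± 55 CPM), TNNC1 (9.98-fold, 2.6 ± 0.156 to 26.1 ± 9.13 CPM) and, at a low level, TNNT2 (12-fold, 0.61 ± 0.0179 to 7.33 ± 1.98 CPM). TNNT2 libraries lay apart already at day 0, at 13 to 26.9 CPM in KO and 3.06 to 11.4 CPM in WT. At day 1 both were lower, at 4.89 to 10.8 CPM in KO and 0.526 to 0.683 CPM in WT. In the WT step from day 0 to day 1, 6 of 25 sarcomere genes fell and 0 rose. In smooth muscle (2 of 16 rose and 1 fell, 6 and 1 over the list alone, adjusted p = 0.000399, adjusted p = 0.411 with an estimated correlation) RGS5 (14.8-fold, 13.4 ± 0.704 to 199 ± 31.3 CPM) rose. Among epicardium genes 3 of 18 rose (3 rose and 1 fell over the list alone, adjusted p = 0.4), of which PODXL (6.35-fold, 138 ± 23.7 to 875 ± 128 CPM) is a sialomucin also found on stem cells. Definitive endoderm genes were lower (3 of 19 fell, 3 over the list alone, adjusted p = 0.00138, adjusted p = 0.681 with an estimated correlation), with HHEX (30.1-fold, 81.4 ± 5.15 to 2.7 ± 1.31 CPM) and FOXA2 (16.3-fold, 57.5 ± 2.35 to 3.52 ± 2.07 CPM). AFP of this list exceeded 5 CPM in 5 of the 11 libraries, both of WT1 and library 3 of WT2, KO1 and KO2. The p53 targets (3 of 20 rose, 6 over the list alone, adjusted p = 2.05e-05, adjusted p = 0.59 with an estimated correlation) were higher, with SESN2 (2.75-fold, 31.6 ± 2.57 to 87 ± 5.83 CPM). Glycolysis and hypoxia genes (2 of 20 rose and 4 fell, 2 and 8 over the list alone, adjusted p = 0.00496, adjusted p = 0.681 with an estimated correlation) were lower on balance, with BNIP3 (2.95-fold, 403 ± 1.71 to 137 ± 17.5 CPM). Extracellular matrix (1 of 20 rose and 3 fell, 2 and 4 over the list alone, adjusted p = 0.00702, adjusted p = 0.475 with an estimated correlation) and mesenchymal genes (1 of 20 rose and 4 fell, 2 and 7 over the list alone, adjusted p = 0.0287, adjusted p = 0.589 with an estimated correlation) ranked lower. So did G2 and M phase (1 of 20 fell, 2 over the list alone, adjusted p = 0.0418, adjusted p = 0.81 with an estimated correlation). The last were histones (no member of 16 passed, nor over the list alone, adjusted p = 0.0207, adjusted p = 0.81 with an estimated correlation) and cholesterol synthesis (1 of 20 fell, 1 over the list alone, adjusted p = 0.0336, adjusted p = 0.797 with an estimated correlation).

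Large rises at day 1 were also seen in SPOCK3 (30-fold, 0.21 ± 0.0693 to 6.18 ± 0.403 CPM), RIPOR2 (22.2-fold), TXNRD2 (20-fold, 1.8 ± 0.744 to 36.5 ± 7.21 CPM), ZIC1 (17.5-fold), CCDC125 (15.7-fold) and WNT10B (15.5-fold, 0.549 ± 0.227 to 8.74 ± 1.4 CPM). Large falls were also seen in KRT20 (ratio 277, counting interval 49.4 to 11000), GIMAP6 (ratio 94.2, counting interval 31.9 to 459), GRAP2 (48-fold, 3.26 ± 2.26 to 0.0657 ± 0.000992 CPM) and KCNV1 (45.8-fold, 8.15 ± 2.06 to 0.175 ± 0.00265 CPM). Day 1 passed 1562 genes, 787 higher and 775 lower, 1020 of them changed at least 2-fold. The 4 lines were apart by genotype for all 1562 and for 56.3% of tested genes, where chance gives 33.3%. Without WT1, WT2, KO1 or KO2 924, 533, 672 and 314 genes passed, the lone line being assumed to vary like the other groups. The log2 that remained without a line is given with each lost call. Without KO2 AJUBA (log2 1.89), APELA (3.91), PDGFRA (-4.41), WNT3A (-3.30) and CLDN3 (1.57) did not pass, and without WT2 NANOG (1.37) did not. CTNNB1 did not pass without KO1 (-0.78) or KO2 (-0.84), nor SOX2 without WT1 (2.91) or WT2 (2.65). CDH2 and NECTIN1 did not pass without WT1 (-1.01 and 1.08), WT2 (-0.88 and 0.89) or KO2 (-0.75 and 0.95), nor ZIC1 (4.05, 4.22 and 3.57). SOX2 did not pass without WT2 library 3 (log2 2.69) or KO1 library 2 (2.65), nor ZIC1 without the latter (3.90). EOMES and MIXL1 did not pass without WT1 (log2 -1.07 and -1.50), WT2 (-1.15 and -1.58) or KO2 (-0.85 and -1.02), nor TBXT and CCN1 without KO2 (-1.41 and 2.12). TNNT2 did not without KO1 (3.87) or KO2 (3.27), nor in limma-voom (3.55). EOMES did not pass on the log2(FPKM + 1) scale (-1.17) or without 5 single libraries (-0.99 to -1.08), nor MIXL1 without KO1 library 2 (-1.36). CLDN3 and GRAP2 did not pass on the log2(FPKM + 1) scale (log2 1.43 and -0.78). DESeq2 passed 2488 genes, limma-voom 2758, the test without the low-count filter 2659 and day 1 fitted alone 4112. With libraries as replicates 2666 passed unblocked and 3226 with a replicate block.

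Day 5 asks whether KO cells reach the cardiac progenitor stage. Cardiac progenitor transcription factors were lower in the lines labelled KO, where 2 of 20 rose and 10 fell (2 and 10 over the list alone, adjusted p = 7.94e-05, adjusted p = 0.411 with an estimated correlation). NKX2-5 (ENSG00000183072.9, chromosome 5, 173232109 to 173235357) fell 68.4-fold from 72.7 ± 10.7 to 1.07 ± 0.504 CPM (adjusted p = 3.69e-07). MEF2C (40.4-fold, 43 ± 29.8 to 1.06 ± 0.0953 CPM), HAND2 (50.6-fold, 59.4 ± 44.1 to 1.18 ± 0.461 CPM) and ISL1 (8.93-fold, 172 ± 31.2 to 19.2 ± 7.45 CPM) fell with it. Cardiac mesoderm genes (2 of 20 rose and 10 fell, 3 and 11 over the list alone, adjusted p = 0.000188, adjusted p = 0.411 with an estimated correlation) included the VEGF receptor KDR (22.6-fold, 758 ± 191 to 33.5 ± 12.8 CPM) and CXCR4 (9.56-fold, 160.2 ± 49.6 to 16.8 ± 8.33 CPM), while RSPO3 (27.8-fold, 0.401 ± 0.211 to 11.8 ± 0.17 CPM) rose. Endothelium and blood genes were lower (1 of 19 rose and 14 fell, 1 and 14 over the list alone, adjusted p = 5.61e-19, adjusted p = 0.0516 with an estimated correlation), with ERG (57.8-fold, 11.3 ± 3.12 to 0.19 ± 0.0756 CPM), TAL1 (79.8-fold, 19.5 ± 5.13 to 0.243 ± 0.0979 CPM) and LMO2 (15-fold, 28.6 ± 4.62 to 1.9 ± 0.0509 CPM). Of sarcomere genes 2 of 25 rose and 6 fell (4 and 7 over the list alone, adjusted p = 0.315). TNNT2 (4.7-fold, 77.3 ± 93.2 to 16.5 ± 0.541 CPM), cardiac troponin T, fell from an uneven WT level, with 526 and 367 CPM in WT2 libraries 1 and 3 and 9.51 to 13.1 CPM in the other 3. This fall was not robust, as without WT2 TNNT2 came to a log2 of 0.54 and within the lower multimapping side of libraries, a grouping made after the data were seen with only KO1 library 2 and KO2 library 3 for KO, to 0.01. Nor did TNNT2 pass in limma-voom (-1.37) or with day 5 fitted alone (-2.26). Calcium handling genes (4 of 24 rose and 4 fell, 4 and 4 over the list alone, adjusted p = 0.83) had a median and mean above 0 and a test pointing down.

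Pluripotency genes were higher in KO at day 5, as 12 of 20 rose (14 over the list alone, adjusted p = 5.67e-17, adjusted p = 0.0175 with an estimated correlation). POU5F1 (ENSG00000204531.16, chromosome 6, 31164337 to 31180731) rose 13.5-fold from 38 ± 3.56 to 513 ± 54.3 CPM (adjusted p = 8.08e-07), with NANOG (46.2-fold, 0.455 ± 0.069 to 20.8 ± 8.73 CPM) and FOXD3 (72.1-fold, 0.109 ± 0.0242 to 7.85 ± 0.589 CPM). SOX2 rose 57.3-fold from 2.17 ± 0.139 to 124 ± 118 CPM, with 395 CPM in KO2 library 3 and 32.4 to 96.6 CPM in the other 5 KO libraries. That library also held 41.4 CPM of PAX6, a neural factor, against 0.689 to 3.11 CPM in the others. Of neuroectoderm genes 6 of 19 rose and 2 fell (8 and 3 over the list alone, adjusted p = 0.106), with SOX3 (29.9-fold, 0.911 ± 0.195 to 27 ± 1.65 CPM) and ZIC2 (3.73-fold, 17.6 ± 2.76 to 65.5 ± 21.8 CPM). The same library held the forebrain factors LHX5 at 230 CPM (0.758 to 6.46 CPM in the other KO libraries) and FEZF1 at 118 CPM (0.124 to 7.27 CPM). Both were among the large rises of the day, LHX5 (135-fold, 0.387 ± 0.0467 to 52.1 ± 71.3 CPM) and FEZF1 (125-fold, 0.212 ± 0.0332 to 27.4 ± 37.1 CPM), beside LHX5-AS1 (ratio 497, counting interval 137 to 4110). Neither passed with day 5 fitted alone (log2 7.06 and 6.95) or without WT1 (7.19 and 6.84) or WT2 (6.96 and 7.17).

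Genes of extraembryonic and surface ectoderm were higher in KO at day 5, as 10 of 18 rose and 1 fell (11 and 1 over the list alone, adjusted p = 2.54e-09, adjusted p = 0.0835 with an estimated correlation). Among them were GABRP (33.9-fold, 1.53 ± 0.388 to 52.8 ± 17.3 CPM), KRT7 (45-fold, 1.12 ± 0.488 to 51.9 ± 0.886 CPM) and TFAP2C (18.9-fold, 1.75 ± 0.402 to 32.9 ± 3.86 CPM). Extracellular matrix genes (6 of 20 rose and 4 fell, 6 and 4 over the list alone, adjusted p = 0.0245, adjusted p = 0.589 with an estimated correlation) included COL3A1 (57.2-fold, 5.77 ± 6.88 to 336 ± 47.3 CPM). Its libraries overlapped, with 2.28 CPM in KO2 library 3 and 29.1 CPM in KO1 library 2, against 26.4 and 40.1 CPM in WT2 libraries 1 and 3. In the libraries of day 5 with the lower share of multimapped reads, a grouping made after the data were seen, MMP2, LUM and COL6A3 turned direction (log2 -0.34, -0.25 and -1.43). The KO side of that grouping is only KO1 library 2 and KO2 library 3, and the latter stood apart as given above, so the turn cannot be laid to multimapping. Tight junction genes (10 of 24 rose, 12 over the list alone, adjusted p = 0.000134, adjusted p = 0.59 with an estimated correlation) included EZR (2.79-fold, 147 ± 18.4 to 410.2 ± 15.2 CPM). Among YAP and TEAD targets 9 of 22 rose and 2 fell (10 and 2 over the list alone, adjusted p = 0.0126, adjusted p = 0.681 with an estimated correlation). Here CCN1 (2.8-fold, 46.4 ± 6.31 to 129.7 ± 24.4 CPM) and AXL (2.15-fold, 93.2 ± 13 to 201 ± 4.37 CPM) rose while TGFB2 (7.12-fold, 52.8 ± 16.8 to 7.42 ± 1.07 CPM) fell. Without KO1 CCN1 did not pass (log2 1.28), nor WWC2 below (0.83). Of adherens junction genes 8 of 23 rose and 2 fell (8 and 2 over the list alone, adjusted p = 0.11), with the actin linker VCL (3.22-fold, 179 ± 6.78 to 578 ± 128 CPM) and the endothelial cadherin CDH5 (34.5-fold, 23.6 ± 7.75 to 0.683 ± 0.277 CPM). Hippo components (8 of 26 rose and 1 fell, 10 and 2 over the list alone, adjusted p = 0.1) included WWC2 (2.02-fold, 115 ± 14 to 233 ± 39.4 CPM). Mesenchymal genes went both ways (6 of 20 rose and 4 fell, 7 and 5 over the list alone, adjusted p = 0.614), with TWIST1 (4.46-fold, 33.7 ± 3.21 to 7.56 ± 3.26 CPM) among those that fell. Smooth muscle genes (5 of 16 rose and 2 fell, 7 and 2 over the list alone, adjusted p = 0.0314, adjusted p = 0.64 with an estimated correlation) and p53 targets (8 of 20 rose, 10 over the list alone, adjusted p = 0.000545, adjusted p = 0.681 with an estimated correlation) ranked higher. So did cholesterol synthesis (5 of 20 rose, 8 over the list alone, adjusted p = 0.00681, adjusted p = 0.726 with an estimated correlation). Primitive streak genes ranked lower (4 of 22 rose and 8 fell, 4 and 8 over the list alone, adjusted p = 0.0357, adjusted p = 0.677 with an estimated correlation), with LHX1 (22.1-fold, 73.7 ± 24.5 to 3.33 ± 1.42 CPM). So did paraxial mesoderm genes (2 of 20 rose and 9 fell, 3 and 9 over the list alone, adjusted p = 0.00124, adjusted p = 0.376 with an estimated correlation), with PAX1 (507-fold, 66.4 ± 5.2 to 0.125 ± 0.0939 CPM). Definitive endoderm genes did not pass (5 of 19 rose and 3 fell, 7 and 3 over the list alone, adjusted p = 0.411). In that list APOA1 (55.3-fold, 5.54 ± 1.3 to 306 ± 35.4 CPM) and FGB (157-fold, 0.543 ± 0.212 to 82.4 ± 5.79 CPM), made in liver and yolk sac, rose and HHEX (13.5-fold, 86.1 ± 25.4 to 6.37 ± 1.86 CPM) fell.

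Other large rises at day 5 were GSTA3 at least 84.8-fold (no count in WT), NNMT (267-fold, 0.0694 ± 0.0685 to 21.8 ± 4.05 CPM), TDO2 (112-fold, 0.0656 ± 0.0557 to 6.83 ± 2.3 CPM) and NRK (107-fold, 0.231 ± 0.0299 to 24.8 ± 5.34 CPM). Other large falls were the endothelial selectin SELE (384-fold, 18.8 ± 6.02 to 0.0456 ± 0.00929 CPM), CD93 (ratio 330, counting interval 112 to 1600), RIPPLY1 (ratio 233, counting interval 79.5 to 1130) and UNCX (ratio 232, counting interval 79.2 to 1130). They included also GIMAP8 (ratio 206, counting interval 56.6 to 1700), GIMAP4 (ratio 150, counting interval 51 to 729) and NKX2-1 (135-fold, 7.95 ± 2.35 to 0.0575 ± 0.0568 CPM). NNMT and FGB did not pass in limma-voom (log2 5.75 and 6.59). Within the lower multimapping side APOA1 and FGB did not pass (log2 4.13 and 4.58), and within the higher side CDH5, FEZF1 and SELE did not (-1.46, 4.57 and -0.86). Day 5 passed 5864 genes, 3542 higher and 2322 lower, 3357 of them at least 2-fold. The excess of higher genes was lost with libraries as replicates (4055 higher and 3917 lower unblocked, 4247 and 4272 with a replicate block), and limma-voom gave 3680 higher and 4150 lower. Lines were apart for 63.2% of tested genes (33.3% by chance). Without WT1, WT2, KO1 or KO2 3680, 3677, 2613 and 2767 genes passed.

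Day 14 asks whether KO cells express the cardiomyocyte programme. Sarcomere genes were lower in the lines labelled KO, where 25 of 25 fell (25 over the list alone, adjusted p = 5.78e-50, adjusted p = 0.0175 with an estimated correlation). MYH6 (ENSG00000197616.11, chromosome 14, 23381990 to 23408277), the atrial myosin heavy chain, fell 3230-fold from 3207 ± 993 to 0.984 ± 0.674 CPM (adjusted p = 3.83e-05). TNNT2 (53.2-fold, 1776 ± 356 to 33.4 ± 1.55 CPM), MYBPC3 (349-fold, 555 ± 69.6 to 1.59 ± 0.428 CPM), MYL7 (90.2-fold, 7008 ± 1660 to 77.7 ± 28.6 CPM) and ACTN2 (158-fold, 561 ± 37.4 to 3.56 ± 0.253 CPM) fell with it. Of these 25 genes none is held by another list, and 23 exceed 10 CPM in WT at day 14. Calcium handling genes were lower as well (2 of 24 rose and 17 fell, 2 and 17 over the list alone, adjusted p = 6.03e-14, adjusted p = 0.0389 with an estimated correlation). Among them were the potassium channel KCNH2 (15.2-fold, 92.2 ± 23.2 to 6.06 ± 1.2 CPM), the calcium release channel RYR2 (5.47-fold, 576 ± 227 to 105 ± 5.07 CPM) and the natriuretic hormone NPPA (97.8-fold, 20 ± 8.77 to 0.203 ± 0.0398 CPM). RYR2 did not pass without KO1 (log2 -2.54) or KO2 (-2.40). Progenitor transcription factors (2 of 20 rose and 13 fell, 2 and 13 over the list alone, adjusted p = 6.44e-08, adjusted p = 0.282 with an estimated correlation) included NKX2-5 (1470-fold, 498 ± 125 to 0.333 ± 0.177 CPM) and MEF2C (45.1-fold, 225 ± 45.7 to 4.99 ± 0.215 CPM). Smooth muscle genes were lower (3 of 16 rose and 9 fell, 3 and 9 over the list alone, adjusted p = 0.00148, adjusted p = 0.475 with an estimated correlation), with MYH11 (19.5-fold, 26.2 ± 3.48 to 1.34 ± 0.105 CPM) and ACTA2 (17.5-fold, 639.9 ± 366 to 36.6 ± 5.82 CPM), and PDGFRB (15.9-fold, 9.49 ± 4.83 to 149 ± 9.19 CPM) rose. Mitochondrially encoded genes (6 of 13 fell, 7 over the list alone, adjusted p = 0.00312, adjusted p = 0.699 with an estimated correlation) included MT-ND3 (3.41-fold, 215 ± 112 to 62.9 ± 0.153 CPM). They took 1.98 ± 0.96% of counts in WT libraries (SD, n = 5) and 0.69 ± 0.09% in KO libraries (n = 6). WT2 libraries 2 and 3, at 2.99 and 3.07%, carry much of the WT mean, and the other 3 WT libraries held 1.07, 1.39 and 1.40%. Other library measures moved with genotype at day 14 too. Alignments outside genes made up 34.0 ± 3.78% in WT and 27.66 ± 2.31% in KO, ambiguous ones 17.02 ± 2.49% and 13.88 ± 1.69%, and RN7SL and RN7SK RNA 3.69 ± 1.09% and 2.27 ± 0.37% of counts. The same 2 WT2 libraries had the highest shares outside genes, 37.93 and 38.07%, against 30.01 to 32.73% in the other WT libraries.

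Extracellular matrix genes were higher in KO at day 14, as 17 of 20 rose (17 over the list alone, adjusted p = 1.28e-20, adjusted p = 0.0175 with an estimated correlation). DCN (ENSG00000011465.16, chromosome 12, 91140484 to 91183123), a matrix proteoglycan, rose 1150-fold from 0.288 ± 0.324 to 369 ± 24 CPM (adjusted p = 3.88e-09), with COL6A3 (75.9-fold, 7.83 ± 1.74 to 591 ± 237 CPM), COL3A1 (25.3-fold, 291 ± 62 to 7385 ± 1560 CPM) and COL1A1 (15.1-fold, 53.1 ± 10.7 to 801 ± 36.4 CPM). Trophectoderm, amnion and surface ectoderm genes were higher (15 of 18 rose and 1 fell, 15 and 1 over the list alone, adjusted p = 3.44e-18, adjusted p = 0.0175 with an estimated correlation). They included GABRP (1090-fold, 1.23 ± 1.19 to 1250 ± 291 CPM), the trophoblast hormone subunit CGA (853-fold, 0.374 ± 0.224 to 304 ± 122 CPM), VTCN1 (183-fold, 1.18 ± 0.509 to 210 ± 8.16 CPM) and ITGB6 (30.6-fold, 9.98 ± 6.07 to 302 ± 37.9 CPM), and ISL1 (6.29-fold, 105 ± 70.9 to 16.6 ± 6.28 CPM) fell. Of this list 6 members are held by another list, 5 exceed 10 CPM in WT, and TP63 lay at 6.12 ± 3.66 CPM in WT and 26.2 ± 35.3 CPM in KO (adjusted p = 0.149). The KO level of TP63 came from KO2 library 3, and without the third KO2 libraries of days 5 and 14 TP63 was lower in KO (log2 -2.67, adjusted p = 0.00655). Definitive endoderm and liver genes were higher (15 of 19 rose and 1 fell, 16 and 1 over the list alone, adjusted p = 3.21e-05, adjusted p = 0.589 with an estimated correlation), with AFP (38.7-fold, 939 ± 1210 to 36340 ± 20300 CPM), TTR (129-fold, 38.8 ± 43 to 4989 ± 3280 CPM) and APOA2 (175-fold, 10 ± 12.1 to 1713 ± 1120 CPM). AFP differed between libraries of a genotype. It stood at 40100 to 51300 CPM in 5 KO libraries and 232 CPM in KO2 library 3, and at 5.11 to 1980 CPM in WT. That KO2 library also held 54.0 CPM of PAX6 against 1.2 to 2.6 CPM in the other KO libraries. Epicardium genes (12 of 18 rose, 12 over the list alone, adjusted p = 5.3e-06, adjusted p = 0.0516 with an estimated correlation) included BNC1 (15.8-fold, 6.86 ± 4.03 to 107 ± 8.46 CPM). Mesenchymal genes (10 of 20 rose and 3 fell, 10 and 4 over the list alone, adjusted p = 8.03e-05, adjusted p = 0.282 with an estimated correlation) included MMP2 (19.9-fold, 51.9 ± 8.74 to 1034 ± 190 CPM) and SNAI2 (18-fold, 2.77 ± 0.688 to 49.3 ± 0.709 CPM).

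Junction, Hippo and proliferation genes also differed at day 14. Tight junction genes were higher (19 of 24 rose and 1 fell, 19 and 1 over the list alone, adjusted p = 1.68e-08, adjusted p = 0.408 with an estimated correlation), with OCLN (5.9-fold, 16.6 ± 8.6 to 97.2 ± 21.8 CPM). Among adherens junction genes 9 of 23 rose and 5 fell (10 and 5 over the list alone, adjusted p = 0.476). There NECTIN3 (2.31-fold, 47.6 ± 1 to 109.8 ± 11.6 CPM) rose, and the heart and testis catenin CTNNA3 (21.1-fold, 237 ± 77.2 to 11.2 ± 1.43 CPM) and CDH2 (2.66-fold, 706 ± 11.9 to 266 ± 47.9 CPM) fell. Hippo components (15 of 26 rose and 2 fell, 15 and 2 over the list alone, adjusted p = 0.00497, adjusted p = 0.603 with an estimated correlation) included TEAD1 (1.97-fold, 161 ± 11.9 to 317 ± 29.5 CPM) and AMOT (4.05-fold, 63.6 ± 37.9 to 257 ± 19.5 CPM). YAP and TEAD targets went both ways (13 of 22 rose and 2 fell, 14 and 3 over the list alone, adjusted p = 0.00221, adjusted p = 0.59 with an estimated correlation), with AXL (2.89-fold, 89.6 ± 10.4 to 259 ± 44 CPM) and ANKRD1 (6.07-fold, 536 ± 399 to 88.2 ± 16.9 CPM). CCN2 lay at 99.2 ± 68.8 CPM in WT and 55 ± 14.6 CPM in KO (adjusted p = 0.0761). Of that list 5 members are held by another list. G2 and M phase genes were higher (16 of 20 rose, 19 over the list alone, adjusted p = 1.76e-05, adjusted p = 0.603 with an estimated correlation), with the proliferation marker MKI67 (2.29-fold, 66.3 ± 14.5 to 152 ± 24.9 CPM). S phase genes (3 of 20 rose, 2 over the list alone, adjusted p = 0.397) and p53 targets (8 of 20 rose and 1 fell, 10 and 1 over the list alone, adjusted p = 0.0647) did not pass as lists.

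The other lists did not pass at day 14. Of pluripotency genes 5 of 20 rose and 1 fell (5 and 1 over the list alone, adjusted p = 0.147), with L1TD1 (29.7-fold, 1.31 ± 0.574 to 37.9 ± 16.5 CPM), and POU5F1 lay at 1.32 ± 0.694 CPM in WT and 1.95 ± 0.205 CPM in KO. In the primitive streak list 3 of 22 rose and 4 fell (3 and 4 over the list alone, adjusted p = 0.808), with CDX2 (39.7-fold, 1.3 ± 1.59 to 48.2 ± 15.9 CPM). For cardiac mesoderm 3 of 20 rose and 5 fell (3 and 5 over the list alone, adjusted p = 0.411), with HAND1 (3.59-fold, 72.6 ± 31.1 to 261 ± 59.9 CPM) and KDR (4.58-fold, 198 ± 7.22 to 43.2 ± 16.5 CPM). In paraxial mesoderm 1 of 20 rose and 8 fell (3 and 8 over the list alone, adjusted p = 0.151). Of endothelium and blood genes 4 of 19 rose and 8 fell (5 and 10 over the list alone, adjusted p = 0.109), with TEK (21.1-fold, 5.09 ± 0.675 to 107 ± 9.92 CPM) and LMO2 (28.1-fold, 43.9 ± 13.8 to 1.56 ± 0.603 CPM). Of neural genes 5 of 19 rose and 4 fell (5 and 6 over the list alone, adjusted p = 0.297), where the median and mean were above 0 and the test pointed down. Canonical Wnt targets (2 of 18 rose and 4 fell, 2 and 4 over the list alone, adjusted p = 0.462) included APCDD1 (14.2-fold, 50 ± 13.3 to 3.5 ± 3.52 CPM). Glycolysis and hypoxia genes (6 of 20 rose and 7 fell, 6 and 7 over the list alone, adjusted p = 0.646) included PDK1 (14-fold, 845 ± 60.7 to 60.5 ± 6.95 CPM) and NDRG1 (32-fold, 20.5 ± 12 to 662 ± 320 CPM), and their mean alone lay above 0. Cholesterol synthesis went both ways (4 of 20 rose and 3 fell, 4 and 4 over the list alone, adjusted p = 0.767), and its median alone lay above 0. Among replication-dependent histones no member of 16 passed (nor over the list alone, adjusted p = 0.513).

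Among the large rises at day 14, in no order of size, were HHLA2 at least 189-fold, TMEM207 at least 132-fold, KRT23 at least 124-fold, TRD-AS1 at least 77-fold, FETUB at least 52.4-fold and MGP at least 48.4-fold, each with no count in WT and so only a lower bound, and MEP1A (ratio 1810, counting interval 324 to 71300) and URAD (ratio 1570, counting interval 282 to 62200). Large falls besides MYH6 and NKX2-5, also in no order, were LRRC10 (ratio 5440, counting interval 976 to 215000), the myosin chaperone UNC45B (3260-fold, 558 ± 58.6 to 0.169 ± 0.0543 CPM), muscle creatine kinase CKM (1470-fold, 219 ± 42.9 to 0.146 ± 0.0217 CPM), PPP1R3A (1290-fold, 91 ± 35.6 to 0.0685 ± 0.0661 CPM) and ASB2 (1170-fold, 187 ± 40.7 to 0.155 ± 0.0889 CPM). COX6A2, with no count in KO, fell at least 353-fold. Day 14 passed 9071 genes, 5146 higher and 3925 lower, 5945 of them at least 2-fold. The excess of higher genes shrank with another scaling, to 4712 higher and 4306 lower with RLE size factors and 4756 and 4507 in DESeq2. Lines were apart for 58.5% of tested genes (33.3% by chance). Without WT2 5887 and without KO1 5291 genes passed, and with day 14 fitted alone 4021.

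**Figure D3:**
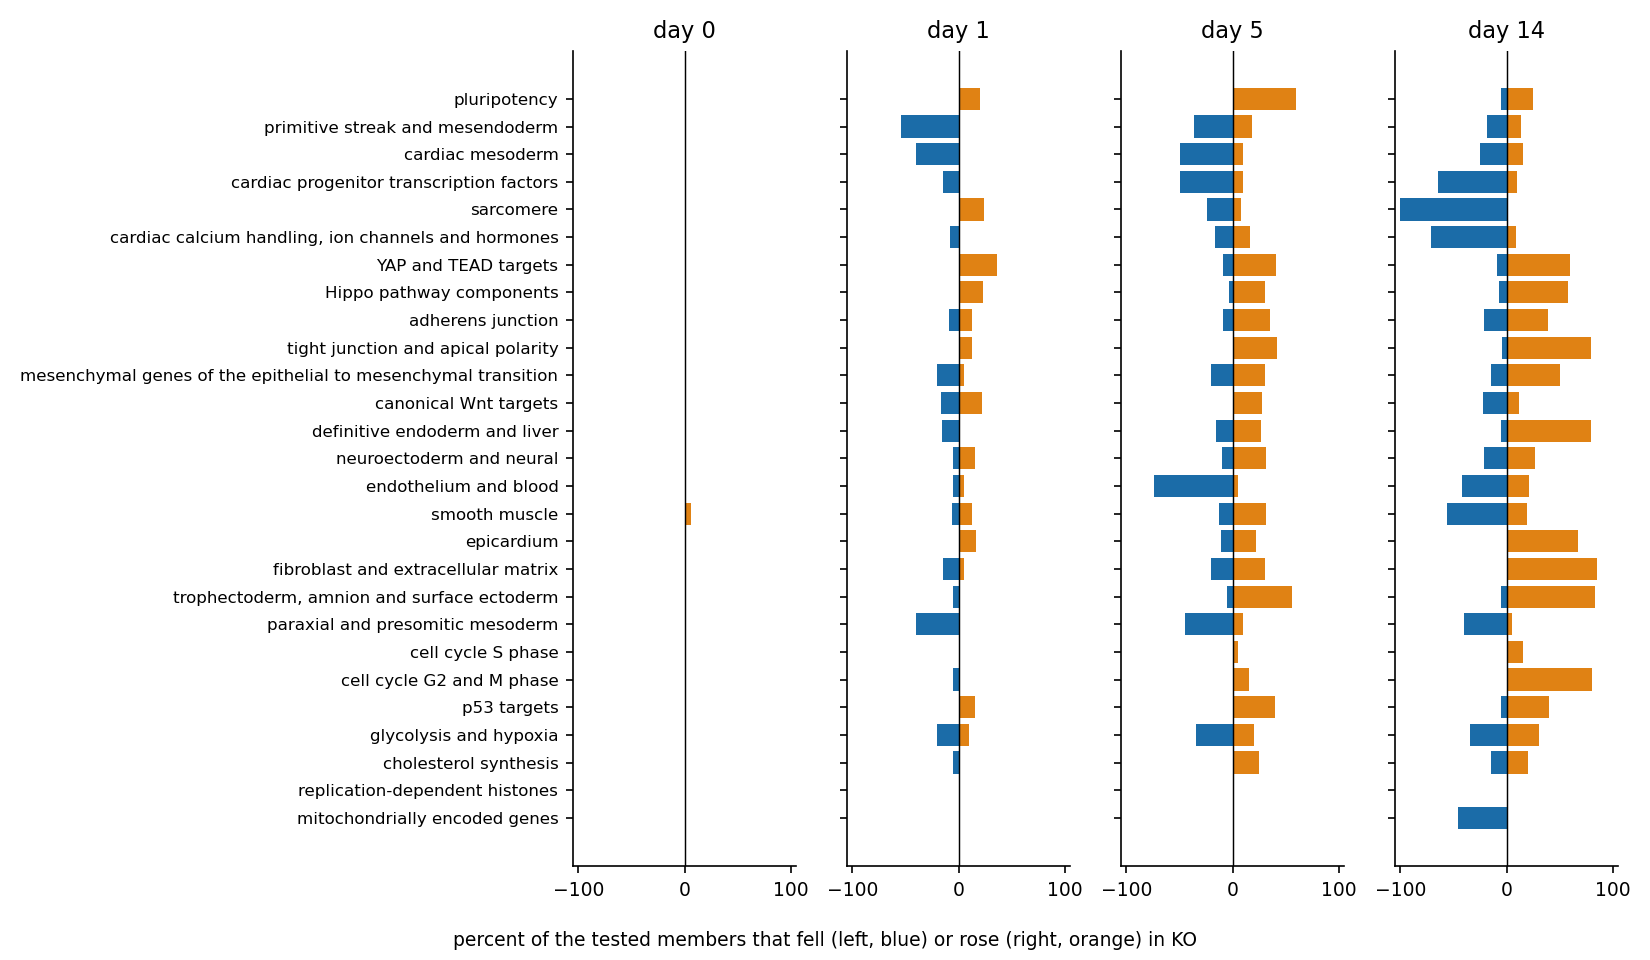
Percent of the tested members of each of the 27 gene lists that fell (bars to the left) or rose (bars to the right) in KO against WT, with 1 panel per day. All 25 sarcomere genes fell at day 14, 12 of 20 pluripotency genes rose at day 5 and 12 of 22 primitive streak genes fell at day 1.

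Over the 27 lists and 4 days, 52 of 108 tests passed at the preset correlation and 7 with an estimated one. The 7 were primitive streak and paraxial mesoderm at day 1, pluripotency at day 5, and sarcomere, calcium handling, extracellular matrix and trophectoderm at day 14. Signs of median, mean and test also differed, with no test passing, for primitive streak, progenitor factors, epicardium, trophectoderm and paraxial mesoderm at day 0. The same held for calcium handling and endothelium at day 1 and for glycolysis and histones at day 5.

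The interaction asks whether KO and WT changed differently between consecutive days. From day 0 to day 1 the KO lines gained less of several mesoderm genes. TBX6 differed by -4.15 ± 0.51 on the log2 scale (primitive streak, 2 of 22 negative, 6 over the list alone). LFNG differed by -2.77 ± 0.35 and DLL3 by -2.86 ± 0.43 (paraxial mesoderm, 3 of 20 negative, 5 over the list alone). CDH2 differed by -1.72 ± 0.27, RNF43 by 3.18 ± 0.37 and PODXL by 2.46 ± 0.30. From day 1 to day 5 pluripotency genes (8 of 20 positive, 9 over the list alone) decreased less in KO, with POU5F1 at 3.94 ± 0.29 and NANOG at 3.75 ± 0.55. Endothelium and blood genes (9 of 19 negative, 15 over the list alone) gained less. So did KDR (-3.65 ± 0.38) and the heart factors NKX2-5 (-8.24 ± 0.83) and MEF2C (-4.87 ± 0.69). Trophectoderm genes (7 of 18 positive, 7 positive and 1 negative over the list alone) gained more, with GABRP at 5.78 ± 0.58. From day 5 to day 14 the differences lay in sarcomere genes (22 of 25 negative, 24 over the list alone), with MYOM1 at -8.74 ± 0.38. They lay also in calcium handling genes (3 of 24 positive and 17 negative, 3 and 19 over the list alone) and extracellular matrix genes (13 of 20 positive and 1 negative, 13 and 1 over the list alone), with DCN at 10.06 ± 0.66. POU5F1 differed by -3.24 ± 0.34.

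The interaction tests passed 153 genes (85 positive, 68 negative), 1714 (1099 and 615) and 6235 (3213 and 3022). For the first and second DESeq2 passed 636 and 2976 and limma-voom 303 and 2816. Without WT1, WT2, KO1 or KO2 the first count was 34, 15, 39 and 1 and the second 799, 697, 449 and 446. The last count was 2797 without KO1 and 3297 without KO2. Single day 0 libraries moved the first count to 81 (without WT1 library 1), 68 (WT2 library 1), 95 (KO1 library 3) and 99 (KO2 library 3). Single day 1 libraries moved it to 84 (WT2 library 3), 82 (KO1 library 2) and 278 (KO1 library 3). Single day 5 libraries moved the second count to 764 (WT2 library 2), 1122 (KO2 library 2) and 2918 (KO2 library 3).

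Across days, 11 of the 16 genes higher in KO at day 0, RGS5 and CCDC125 among them, were also higher at day 1 (0.4 by chance). Of the genes that changed at day 1, 409 higher ones (99.4 by chance) and 257 lower ones (64.1) had the same direction at day 5, and 51 of each the opposite one. Days 5 and 14 shared 1278 higher (649.7 by chance) and 698 lower genes (324.9), and 435 and 343 had the opposite direction. Of genes lower at day 1, 166 were lower at day 14 (108.4 by chance) and 194 higher. Of those higher at day 1, 292 were higher (144.4) and 136 lower. Chance is for the same direction and independent days, but days share lines. The KO lines were also compared through separate WT lines. Across genes, KO1 minus WT1 and KO2 minus WT2 correlated with r of 0.17, 0.528, 0.681 and 0.685 at days 0, 1, 5 and 14. The other pairing gave 0.149, 0.523, 0.677 and 0.727, and WT2 minus WT1 against KO2 minus KO1 gave 0.023, 0.006, 0.007 and -0.064. Genes are not independent replicates in these correlations.

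Line against line, KO1 and KO2 differed in few genes besides NF2. At day 0 there were 5, among them NF2 (log2 -2.59 for KO2 minus KO1), the imprinted gene PEG3 (0.0275 CPM in KO1 and 35.4 CPM in KO2), CCDC152 and ZNF572, and at day 1 the same 5. Day 5 gave 10, adding the imprinted gene NNAT, NPFFR2, PKIB, RAD51C and 1 antisense gene, and day 14 gave 4, with NF2, PEG3 and NNAT among them. A replicate block gave 3 at day 0 and 7 at day 1. At an unadjusted p under 0.05 there were 337, 522, 1281 and 1615. WT1 and WT2 differed in 5, 10, 72 and 112 genes (322, 482, 1666 and 3809 unadjusted). The block gave 6 and 7 at days 0 and 1 and fewer than 72 and 112 at days 5 and 14. At day 0 the 5 were CHCHD2 (0.0277 CPM in WT1, 178 CPM in WT2), ZNF619, CCDC152, PEG3 and ZNF572. The last 3 differed the same way between KO1 and KO2, and no fit pairs lines. Genes here were named after their values were seen.

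Single libraries moved the counts between lines. Leaving 1 out leaves a line with a single library at day 0, and WT1 at each day, and that library is assumed to vary like the other groups. Between KO1 and KO2, 2 or 3 genes passed without any 1 of the 4 libraries of day 0, and 8 passed without KO1 library 1 of day 1. At day 5 26 and 158 passed without KO2 library 1 and 2, and at day 14 47 and 24. Between WT1 and WT2 the counts ran from 1 to 4 at day 0, 2 to 5 at day 1, 3 to 943 at day 5 (943 without WT2 library 2) and 3 to 2301 at day 14. At day 14 2301 genes passed without WT2 library 1 and 58 without WT1 library 2.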

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

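The tests of carried-over RNA, of the sarcomere genes at day 1 and of the KO2 libraries numbered 3, and the sorting of splits by replicate number, were chosen only after the results were seen. The counts of other splits were chosen before. Single extreme libraries were not tested within these groups of 2 or 3 libraries.

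The first results met the rule of a difference between groups, since the change of KO against WT was tested between consecutive days. It differed in 153 genes from day 0 to day 1, in 1714 from day 1 to day 5 and in 6235 from day 5 to day 14. KO1 and KO2 differed from each other in 5, 5, 10 and 4 genes at days 0, 1, 5 and 14. The log2 difference in NF2, KO2 minus KO1, was -2.59, -2.18, -2.34 and -2.48 at these days.

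Splits of the samples were counted for the comparisons of lines. The 4 lines make 3 splits into 2 and 2, too few for a share under 0.05; the labels gave 17, 1562, 5864 and 9071 genes at days 0, 1, 5 and 14. In edgeR each other split gave 0 genes at each day, and 1 of the 3 splits, the real one, gave as many as the labels. Each other split puts 1 KO and 1 WT line in each group. A difference between KO and WT then adds to the spread within groups and lowers the count. The counts of the other splits are therefore no measure of what chance gives. At an unadjusted p under 0.05 the other splits gave 304 and 307 genes at day 0, 142 and 151 at day 1, 225 and 256 at day 5 and 742 and 1309 at day 14, against 1803, 5175, 9321 and 11668 by the labels. The 6 KO libraries of a day make 10 splits into 3 and 3, also too few. At day 1, 1 of the 10 gave as many genes as KO1 against KO2, with 5 by the labels and 0 as the highest other. Equal replicate numbers may pair these libraries (r = 0.366 and 0.301 for numbers 2 and 3, 0.092 for number 1). The 3 other splits that also part all 3 numbers gave 0 genes in edgeR and 358 to 601 at an unadjusted p under 0.05, against 522 by the labels, and the 6 that part 1 number gave 0 and 462 to 1662. With a replicate block the labels gave 7 genes. At day 14 the labels gave 4, 1 of the 10 splits gave as many, and the highest other gave 2. At day 5 the labels gave 10 and 3 of the 10 splits as many, the highest other 647. That split set KO1 libraries 1 and 3 with KO2 library 2, at 13.4, 26.3 and 53.9 CPM of AFP, against KO1 library 2 with KO2 libraries 1 and 3, at 6.36, 13.2 and 5.79 CPM. It points to a structure of the samples that cuts across the lines.

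AFP, COL3A1, APOB and other genes of the KO cells of day 14 appeared at low levels in 5 of the 11 libraries of day 1 and in the 4 libraries numbered 3 of day 0. Carry-over from the KO libraries of day 14 would give each gene the same share of its KO level there, and in the day 1 libraries 19 of 22 genes, 86.4%, lay within 2-fold of the median share of 2.54 per 10000, so carry-over is a candidate explanation there. RNA carried over from the WT libraries of day 14 would bring cardiac genes, whose median share was 0.00719 per 10000 (quartiles -0.564 and 1.87), which argues against it. In the day 0 libraries 12 of 17 genes, 70.6%, lay within 2-fold of the median of 3.19 per 10000, between the bounds set for the test, so carry-over and expression in these libraries cannot be told apart. None of the 17 genes called at day 0 and none of the 1562 called at day 1 owed over 0.1 of its level to such a share.

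Sarcomere genes such as TPM1, TNNC1 and TNNT2 were higher in KO at day 1, and cells like the WT cells of day 14, or their RNA, would raise each by the same share of its WT level at day 14. The shares of the 5 members that rose and reached 1 CPM ran from 0.379 to 7.56%, a 19.9-fold range, which argues against that source. At their median share of 1.43% MYH6 would have stood at 45.8 CPM, and it lay at 0.702 CPM in KO. The test did not use day 0, where TNNT2 already lay at 13 to 26.9 CPM in KO libraries and 3.06 to 11.4 CPM in WT. The KO libraries of day 1 held less TNNT2, 4.89 to 10.8 CPM, so for TNNT2 the difference is no gain over day 0. A first version of this test asked how many abundant members stayed under 0.1 of the level that share gives; it came to 10 of 20, met neither of its bounds, and was replaced after its result was seen. Merlin's loss in the lines labelled KO stays open as a biological explanation and was not tested.

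KO2 library 3 of day 5 and KO2 library 3 of day 14 stood apart from the other KO2 libraries of their days, as with PAX6 at 41.4 and 54.0 CPM. At day 14 the chi-square of counts per degree of freedom was 229.9 and 214.2 between that library and the 2 others, and 12.2 between those. Both libraries resembled an earlier day. Across genes that of day 14 had r = 0.882 with KO2 and 0.875 with KO1 of day 5, against 0.866 and 0.869 at day 14. That of day 5 had r = 0.918 with KO2 of day 1 and 0.916 with KO2 of day 0, against 0.893 with KO2 of day 5. A library of another line under the KO2 label would carry more NF2; the higher of the 2 held 14.5 CPM, and the lowest library of the other 3 lines held 49.3 CPM. Exchanged day labels would put POU5F1 of day 5 cells in the library of day 14, which held 2.39 CPM, against 415 CPM in the lowest other KO library of day 5. It would also bring the library labelled day 5 near day 14, and its r with KO2 of day 14 was 0.761. These values argue against another line and against an exchange.

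A single wrong day label was tested on the genes at least 16-fold apart between 2 days in the other KO libraries. In the KO2 library labelled day 14, 76 of 149 such genes, 51.0%, lay within 2-fold of the range of day 5 and 22.1% within that of day 14, between the bounds set for the test. A further test, added after this result was seen, counted genes over 4-fold beyond the range of all 6 KO libraries of day 5, towards day 14. They were 39 of 133, 29.3%, against at most 2.0% when each KO library of day 5 was set against the others. NANOG (0.14 CPM, 9.83 CPM or more at day 5) and GABRP (2160 CPM, 195 CPM or less) were outside that range too. These values argue against a day 5 library under that label. In the library labelled day 5, 37.3% of 67 genes lay near day 1 and 24.4% of 82 near day 0. Fewer, 11.9 and 14.6%, lay near other libraries of day 5, so the test cannot decide. A different course of differentiation in these cultures stays open and was not tested.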

How the results depend on the processing

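The splits of libraries by AFP and by multimapping, the thinning of line sums and the omission of KO2 library 3 of days 5 and 14 were chosen only after the data were seen, and the other alternatives before.

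For the counts below the cause was not tested, except where fewer samples or counts give it. RLE size factors kept each count of genes within 1.5 times, and across named genes and comparisons gave 1110 the same side of the threshold, 1 a new call and 3 a lost one; NF2 in KO1 at day 5 came to 73.1 CPM against 74.6. Without a low-count filter the counts were 412 at day 0, 2659 at day 1, 948 and 3119 for the first and second interaction, 25, 88, 393 and 354 for KO1 against KO2 and 24, 83, 766 and 1257 for WT1 against WT2 at days 0, 1, 5 and 14. DESeq2 gave 170 and 2488 genes at days 0 and 1 and 636 and 2976 for these interactions, limma-voom 43, 2758, 303 and 2816, and libraries as replicates with a replicate block 50, 3226, 499 and 3519. Unblocked libraries gave 2666 genes at day 1 and 310 and 3038 for the interactions. On the log2(FPKM + 1) scale 61 genes passed at day 0 and 288 for the first interaction, and 92 and 320 with no filter. Each day fitted alone gave 536, 4112 and 4021 genes at days 0, 1 and 14. Without KO2 library 3 of days 5 and 14, 60 and 2454 genes passed at days 0 and 1 and 429 and 3803 for the interactions, and TP63 at day 14 turned direction (log2 -2.67). With the split of libraries as a term 2606 genes passed at day 1. Within the lower and higher AFP side 733 and 1013 passed at day 1, and within the lower multimapping side 2804 at day 5, with fewer samples each. In the latter, with KO1 library 2 and KO2 library 3 alone for KO, MMP2 (log2 -0.34), LUM (-0.25), COL6A3 (-1.43), LSS (-0.18) and TNNT2 (0.01) turned direction, and within the higher side EOMES (0.10) and GJA5 (1.20). At least 2-fold, 1020, 3357 and 5945 genes passed at days 1, 5 and 14. With a replicate block between lines 3 genes passed at day 0 for KO1 against KO2 and 15 and 57 at days 5 and 14 for WT1 against WT2.

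Leaving out a line or a library gave 0 to 37, 314 to 1829, 2613 to 7778 and 5291 to 10441 genes for KO against WT at days 0, 1, 5 and 14, and a line left alone in its genotype, or a library in its line, is assumed to vary like the other groups. In edgeR the counts of 0 at day 0, without WT1, WT2 or KO2, came with 1514, 1951 and 981 genes at an unadjusted p under 0.05 (DESeq2 170 and limma-voom 43 with all lines). For the WT time course they gave 2631 to 7266, 6973 to 11751 and 6523 to 11300, and for the interactions 1 to 278, 446 to 2918 and 2797 to 7802. Between KO1 and KO2 the ranges were 2 to 3, 5 to 8, 7 to 158 and 4 to 47, and between WT1 and WT2 1 to 4, 2 to 5, 3 to 943 and 3 to 2301. Over the named genes of all comparisons, leaving out WT1, WT2, KO1 or KO2 ended 110, 140, 143 and 158 calls, and TNNT2 at day 5 turned direction without WT2. Its log2 ran from -3.80 to 0.54 without a line or a library, against -2.23, and that of TP63 at day 14 from -2.69 (without KO2 library 3) to 3.03, against 2.11. List tests passed 48 to 59 of 108 without a line, against 52, and 7 with an estimated correlation. Correlations of the KO effects across genes with at least 100 counts (14429 genes, not independent replicates) were 0.417, 0.753, 0.795 and 0.82 at days 0, 1, 5 and 14, and 0.335, 0.754, 0.791 and 0.848 in the other pairing.

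Thinned to the depth of the smallest line sum, 5, 1222, 4833 and 8000 genes passed at days 0, 1, 5 and 14, against 17, 1562, 5864 and 9071. In counts simulated at full depth with 200 genes changed, 2-fold changes passed in 33.3, 40.8, 34.5 and 40.9% of genes at these days. Changes of 1.5-fold passed in 1.6, 1.4, 4.3 and 6.8%. The data can differ, as these counts hold few changes, no lasting line differences and no correlation between genes. A floor of 3 counts is 0.064 to 0.616 CPM per library.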

Other observations

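The gene families of this part were chosen only after their values were seen, and no test of an explanation was run for them.

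Nuclear genes of the respiratory chain fell with the heart genes of the report at day 14. Of 70 NDUF, COX and ATP5 genes, 25 rose in KO at day 5, and at day 14 59 fell and 1 rose, with 1 that fell at day 1. At day 14 the ATP synthase subunit ATP5F1B (1620 to 581 CPM, log2 -1.48 ± 0.11), the complex I subunit NDUFS1 (266 to 143 CPM, log2 -0.89 ± 0.10) and COX8A (166 to 93.7 CPM, log2 -0.83 ± 0.12) fell. Of 13 mitochondrially encoded genes 6 fell at day 14, and their list did not pass with an estimated correlation (adjusted p = 0.699). COX6A2, the heart and muscle form of a complex IV subunit, had no count in KO.

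Apolipoprotein genes, expressed in liver and yolk sac, rose with AFP and TTR. Of 10 genes 5 passed as higher in KO at day 5 and all 10 at day 14. At day 14 APOB (88.2 to 5290 CPM, log2 5.91 ± 0.85), APOA4 (1.19 to 1250 CPM, log2 10.03 ± 0.53), APOC3 (2.04 to 454 CPM, log2 7.91 ± 0.63) and APOE (585 to 3660 CPM, log2 2.65 ± 0.30) rose. KO2 library 3 of day 14 held less of the yolk sac and liver genes AFP (232 CPM, others 40100 to 51300 CPM) and TTR (76.5 CPM, others 4200 to 8400 CPM).

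Some HOXB and HOXC genes, which pattern the body axis, were higher in KO. Of 14 tested 7 rose at day 5 and 9 at day 14, and the rest did not pass. Those that rose at day 14 were near absent in WT, such as HOXC8, at 7.67 CPM in KO, and HOXB6, at 7.79 CPM, with so few counts in WT that no fold is given. The more abundant HOXB2 (21.2 CPM in WT, 24.0 CPM in KO, adjusted p = 0.873), HOXB4 (16.7 and 21.4 CPM, 0.842) and HOXB3 (13.5 and 24.3 CPM, 0.43) did not pass. No test of the family was made.

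Some genes set lines apart, given here as CPM of line sums, which differ slightly from library means. CHCHD2 lay at 0.0392 CPM in WT1 at day 0, against 183.6 CPM in WT2, 85.3 CPM in KO1 and 186 CPM in KO2, and at 0.355, 255.5, 99.7 and 186 CPM at day 14. PEG3, an imprinted gene, lay at 0.0273 CPM in KO1, 35.8 in KO2, 11.8 in WT1 and 87.4 in WT2 at day 0. At day 14 library means were 0.239, 11.7, 2.27 and 69.3 CPM in that order. Whether these genes relate to NF2 was not tested.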
